A study of Mus musculus with 8 samples.

How the data were processed

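Colon epithelial cells of C57BL/6J mice of 4 genotypes (wild-type, St6galnac6-/-, B3galt5D116A and B3gnt7-/-) were profiled by RNA sequencing, with 1 male and 1 female library per genotype and 8 libraries in all. Per the labels' protocols, total RNA was taken with the miRNeasy Micro Kit and libraries were made with the TruSeq stranded mRNA kit. The submitters' processing notes name TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18, Cuffdiff 2.2.1 and the mouse genome build mm10, without parameters or an annotation. The authors deposited 1 table per library with FPKM values, fragments per kilobase of transcript scaled to the mapped fragments, for each of 24346 gene symbols, per the file headers. How the libraries were scaled to each other is not stated. No batch, date or replicate number is given in the labels, so a batch cannot be separated from genotype, and libraries are named by genotype and sex.

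The tables hold no counts. A relative depth was computed from values under 0.15 FPKM. For each gene the ratio of such values between a library and the wild-type male library was taken. The most frequent ratio was read as the inverse of the depth ratio. It rested on 740 to 907 genes per library, of which a minority of 27.7% to 33.9% lay within 0.01 of that ratio on the log2 scale. Between 8471 and 9175 genes per library were listed at 0, among them 2 to 4 of 77 ribosomal protein genes, which are abundant in any cell, so a value of 0 may be a failed estimate. The 10 highest genes held 6.63% to 8.54% of each library's FPKM sum. Correlations of log2 values between libraries were 0.974 to 0.986 within a genotype and 0.971 to 0.988 between genotypes.

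Values were taken as log2(FPKM + 1), with a pseudocount of 1. The 11537 genes with a mean of at least 1 FPKM over the 8 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with trend=TRUE), with genotype and sex as additive terms in 1 fit of all 8 libraries, which left 3 residual degrees of freedom and 4.02 prior degrees of freedom. Each mutant was compared with wild-type, the mutants with each other, and males with females, with two-sided tests. P-values were adjusted by Benjamini-Hochberg over the genes of each comparison, with a threshold of 0.05. The spread is estimated over all genotypes and assumed to be alike in each. An interaction of genotype and sex could not be fitted, since each combination had 1 library.

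Before the data were examined, 35 gene lists (glycosylation enzymes, mucins, pathways and markers of epithelial and other cell types), the tests, the alternatives and the rule for naming genes were fixed. By that rule the text names the targeted genes, up to 10 genes per direction with the largest change past the threshold and the same sign in both sexes, filled up to 5 by smallest p with those said not to have passed, and up to 4 members per list that passed or, for a called list, had the smallest p. A list was tested when at least 3 members were, which held for 33; the lists of B and plasma cells and of enteric glia and neurons were not tested. Lists were tested with camera at its preset correlation of 0.01, which asks if a list moved against the other genes, again with an estimated correlation, and with fry, which asks if a list's genes move on balance one way, each adjusted over the 33 lists. Fry's mixed test, which asks if a list's genes change in either direction, was run as well. Members were also counted adjusted over the list alone. The overlap of calls between mutants was set against 100 simulations of unchanged groups, in which the comparisons shared a simulated wild-type pair and each gene was drawn independently.

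Gene positions were taken from the GENCODE M21 annotation of mm10 by symbol, which placed 11094 of the tested genes (96.2%). The test was checked on simulated values of 11537 genes, with 100 genes changed by log2 1 and 100 others by log2 2 in the same fit. It recovered 59%, 72%, 65% and 91% of changes of log2 1 for St6galnac6-/-, B3galt5D116A, B3gnt7-/- and sex. Of changes of log2 2 it recovered 94%, 99%, 96% and 100%, with 7, 16, 6 and 7 false calls among the unchanged genes. Recovery may be lower where fewer genes change, since the adjusted threshold is then stricter. The list test called the 1 list that was moved, and 0 of 20 others. Genes were drawn independently of each other there, so this check does not show how often lists of correlated genes are called falsely.

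The alternatives for counts of genes were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, quantile normalization, median centring, no block term, a fit of only the genotypes compared, a constant or robust prior variance, and each library left out in turn. For lists they were a pseudocount of 0.1, no filter, quantile normalization, no block term and each library left out, and for single genes the same without no filter. Between mutants, the fit of only the genotypes compared was added later. Leaving out small RNA genes was added after seeing the data, and a fit without the B3gnt7-/- female library was also chosen then but is the same fit as the planned one. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for positions and figures. No library was left out.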

Results

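RNA from colon epithelial cells of C57BL/6J mice was sequenced in 8 libraries, for 4 genotypes with 2 libraries each, 1 from a male and 1 from a female. Besides wild-type, the mice were labelled as St6galnac6-/-, for the sialyltransferase St6galnac6, B3gnt7-/-, for the N-acetylglucosaminyltransferase B3gnt7, or B3galt5D116A, for the D116A substitution in the galactosyltransferase B3galt5. All 3 enzymes act on glycans such as those of intestinal mucins, and the comparisons ask how the transcripts of the colon epithelium differ between these genotypes and wild-type. Each library gave 1 FPKM value (fragments per kilobase of transcript, scaled to the mapped fragments) for each of 24346 gene symbols. The FPKM sums ran from 518482 in the B3gnt7-/- female library to 639537 in the B3galt5D116A female library, and 11392 to 11663 genes per library were at 1 FPKM or more. Read counts were not given, so the depth was read from the steps between values under 0.15 FPKM. Relative to the wild-type male library at 1, it was 1.05 in the wild-type female, 1.21 and 1.36 in the St6galnac6-/- male and female, 1.45 and 1.26 in the B3galt5D116A male and female, and 1.40 and 1.18 in the B3gnt7-/- male and female. With counts unknown, no counting interval or detection limit is given, and a value of 0 may be a gene without reads or an estimate that failed. Such genes are called listed at 0. Values are mean ± SD over the male and female library of a genotype (n = 2), and log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of genes at low FPKM. The p-values measure only the spread between these libraries, and the labels do not say whether a library came from 1 animal or a pool.

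The targeted genes were compared first. St6galnac6 (mm10 chromosome 2 from 32599709 to 32620806) was at 368 and 343 FPKM in the male and female wild-type libraries and at 218 and 232 FPKM in the St6galnac6-/- libraries, 59.1% and 67.6% of the wild-type library of the same sex. In the other mutants it was at 495 and 363 FPKM (B3galt5D116A) and 397 and 444 FPKM (B3gnt7-/-). B3gnt7 (chromosome 1 from 86302832 to 86307305) was at 215 and 189.8 FPKM in wild-type, 213 and 265 FPKM in St6galnac6-/-, 266 and 154 FPKM in B3galt5D116A and 68.8 and 142 FPKM in B3gnt7-/-. The B3gnt7-/- values were 32.0% and 74.7% of wild-type of the same sex. B3galt5 (chromosome 16 from 96235801 to 96319859) was at 117 and 105 FPKM in wild-type, 105 and 138 FPKM in St6galnac6-/-, 133 and 93.1 FPKM in B3galt5D116A and 109.6 and 162 FPKM in B3gnt7-/-. Since its allele is a substitution, its transcript level does not check the label. St6galnac6 was thus lowest in both St6galnac6-/- libraries and B3gnt7 in both B3gnt7-/- libraries, but transcript remained. The labels do not say which part of either gene is deleted, and gene-level values cannot show whether that part is present. None passed the limma test in its own mutant. The log2 difference was -0.66 (SE 0.17, adjusted p = 0.340) for St6galnac6. It was -1.03 (SE 0.37, adjusted p = 0.657) for B3gnt7 and 0.01 (SE 0.25, adjusted p = 0.996) for B3galt5. Within 1 Mb of its targeted gene, limma called 0 of 34 tested genes at St6galnac6 (3 at an unadjusted p under 0.05), 0 of 6 at B3galt5 (1 unadjusted) and 0 of 17 at B3gnt7 (1 unadjusted).

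**Figure D1:**
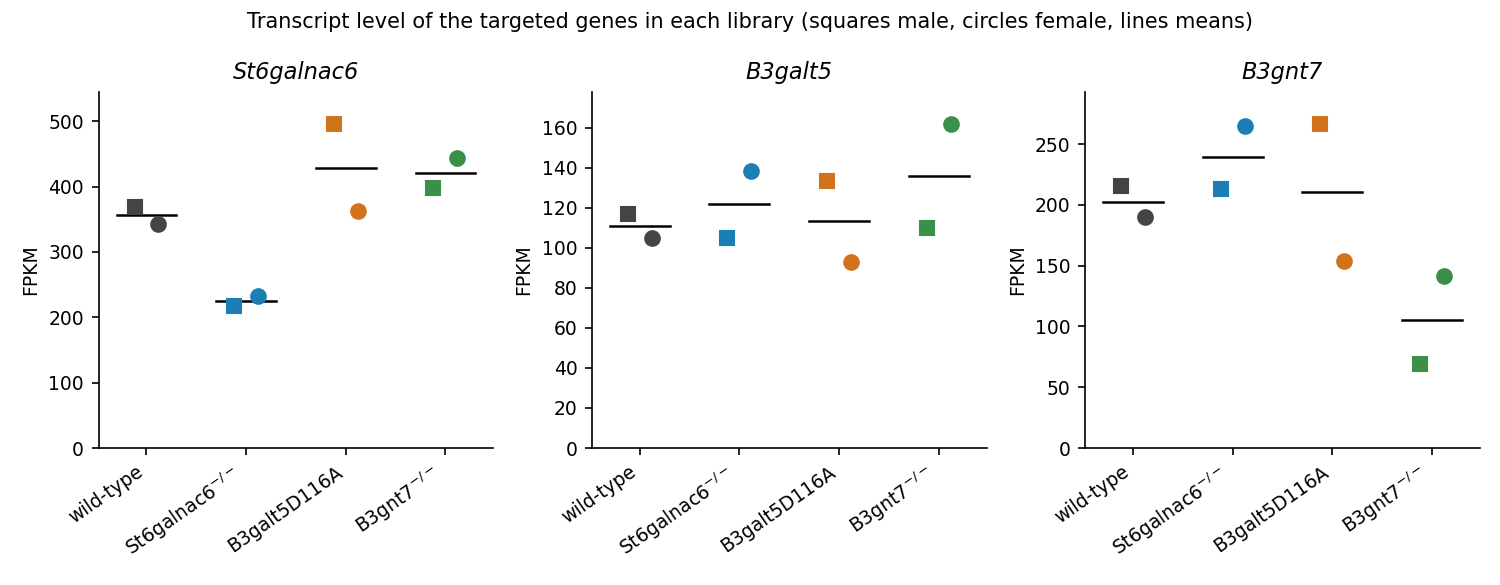
FPKM of St6galnac6, B3galt5 and B3gnt7 in each of the 8 libraries (squares male, circles female), with a line at the mean of each genotype. St6galnac6 was lowest in the St6galnac6-/- libraries (217.6 and 232 FPKM) and B3gnt7 in the B3gnt7-/- libraries (68.8 and 142 FPKM), while B3galt5 in B3galt5D116A (133 and 93.1 FPKM) lay around the wild-type values (117 and 105.0 FPKM).

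The St6galnac6-/- genotype was set against wild-type. Ang4, an antimicrobial ribonuclease made by intestinal secretory cells, rose from 5.77 ± 2.53 FPKM to 259 ± 144 FPKM (n = 2 each), a log2 change of 5.20 (SE 0.57, limma adjusted p = 0.0468). Pla2g2a, a gene of the secreted phospholipase family, rose from 2.69 ± 1.52 FPKM to 15.0 ± 2.21 FPKM (log2 2.18), and Ifitm3, an interferon-induced membrane protein, from 11.8 ± 0.689 FPKM to 24.7 ± 1.23 FPKM (log2 1.001). Fxyd4, a regulator of the sodium pump, fell from 101 ± 12.1 FPKM to 12.5 ± 4.02 FPKM (log2 -2.95), and the keratin Krt36 from 31.2 ± 4.63 FPKM to 4.08 ± 0.763 FPKM (log2 -2.66). The nuclear receptor Nr4a1, an immediate early gene, fell from 321 ± 47.6 FPKM to 117 ± 8.69 FPKM (log2 -1.45), with its relative Nr4a3 (log2 -2.26), the nuclear protein Csrnp1 (log2 -1.58) and the troponin Tnni1 (log2 -1.28). Naip6, of the family of cytosolic sensors of bacterial proteins, fell from 14.2 ± 1.17 FPKM to 0.0801 ± 0.00240 FPKM (log2 -3.81, adjusted p = 0.00398). Naip6 has near-identical paralogs, between which reads are assigned with uncertainty, and Naip5 was at 43.4 and 40.2 FPKM in St6galnac6-/- against 31.2 and 35.5 FPKM in wild-type. Naip7 was listed at 0 in both St6galnac6-/- libraries against 3.69 and 7.04 FPKM, and the sum of Naip5, Naip6 and Naip7 was 43.5 and 40.3 FPKM against 48.3 and 57.6 FPKM. These 10 genes, 3 higher and 7 lower, were all that passed of 11537 tested, each with the same sign in both sexes, with 1043 at an unadjusted p under 0.05, where chance alone gives 577 in any comparison of 11537 genes. Ang4 lies on mm10 chromosome 14 from 51763878 to 51773590, Fxyd4 on chromosome 6 from 117933559 to 117937692, Krt36 on chromosome 11 from 100102007 to 100105626, Nr4a1 on chromosome 15 from 101254269 to 101274795 and Naip6 on chromosome 13 from 100281121 to 100317674. The hormone Insl5 (log2 1.12, adjusted p = 0.0695) and the antigen-presenting chain H2-Aa (log2 1.88, adjusted p = 0.0752) had the smallest p among the higher genes that did not pass.

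Of 33 gene lists tested in St6galnac6-/-, camera with its preset correlation called 11, 6 higher and 5 lower. With an estimated correlation it called 0 (smallest adjusted p = 0.228), beside 1043 single genes at an unadjusted p under 0.05. Of 23 goblet cell genes, 1 rose over all genes, and 10 rose and 0 fell adjusted over the list alone, with a median log2 change of 0.45. For goblet cell genes, camera gave adjusted p = 1.89e-09, and adjusted p = 0.228 with an estimated correlation. Beside Ang4, the secretory lectin Reg4 was at 609 ± 11.3 FPKM against 142 ± 5.81 FPKM, Spink4 at 2806 ± 246 FPKM against 1033 ± 93.1 FPKM and the mucus protein Clca1 at 986 ± 149 FPKM against 209 ± 27.5 FPKM. Muc2, the main secreted mucin, named after its values were seen, had a log2 difference of -0.10 (adjusted p = 0.927). The 7 MHC class II genes had a median of 1.57, with 0 called over all genes and 5 higher adjusted over the list alone. For MHC class II genes, camera gave adjusted p = 1.11e-06, and adjusted p = 0.228 with an estimated correlation. Among them Cd74, the invariant chain, was at 36.6 ± 3.66 FPKM against 7.54 ± 1.40 FPKM. In the same comparison, T and intraepithelial lymphocyte markers had a median of 0.05 (mean -0.04, downward test direction) and myeloid markers of -0.01 (upward test direction), and neither list was called.

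Absorptive colonocyte genes in St6galnac6-/- were negative in 28 of 30, with a median of -0.37, 0 called over all genes and 6 lower adjusted over the list alone. For absorptive colonocyte genes, camera gave adjusted p = 1.79e-07, and adjusted p = 0.228 with an estimated correlation. Examples were the proton pump Atp12a (log2 -1.51), Saa1 (log2 -1.11), Slc37a2 (log2 -2.20) and carbonic anhydrase Car4 (log2 -0.71), none of which passed over all genes. Tight junction genes had a median of -0.15, with 0 called over all genes. Adjusted over the list alone, 4 were lower, occludin Ocln (log2 -0.67) and the claudins Cldn3, Cldn4 and Cldn23. For tight junction genes, camera gave adjusted p = 1.25e-04, and adjusted p = 0.228 with an estimated correlation. Fry for a move one way called this list alone, with adjusted p = 0.0438. Proliferation genes were positive in 30 of 30 with a median of 0.63, 0 called over all genes and 0 adjusted over the list alone. For proliferation genes, camera gave adjusted p = 1.89e-09, and adjusted p = 0.797 with an estimated correlation. Without the St6galnac6-/- female library they no longer passed (median 0.15). Of 30 immediate early and heat shock genes, with a median of -0.44, 1 fell over all genes, and 13 fell and 1 rose adjusted over the list alone. For this list, camera gave adjusted p = 1.91e-06, and adjusted p = 0.649 with an estimated correlation. The 22 immediate early members had a median of -0.56 and the 8 heat shock members of 0.74. Fosb and Atf3, immediate early transcription factors, were at log2 -1.29 and -1.38 without passing over all genes.

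The other lists called in St6galnac6-/- had 0 members called over all genes, and adjusted p = 0.663 or more with an estimated correlation. Stem cell genes had a median of 0.25. Tuft cell genes had 0.35, and no longer passed without the wild-type female (0.16) or the St6galnac6-/- male library (0.33). Interferon response genes had 0.18, and no longer passed without the wild-type female (0.11) or the St6galnac6-/- female library (0.0075, with a downward test direction), or with quantile normalization (0.17, adjusted p = 0.095). Cholesterol synthesis genes had -0.15, with Hsd17b7 lower adjusted over the list alone. Their median turned positive without the wild-type male (0.10) or the St6galnac6-/- male library (0.02). Xenobiotic metabolism genes had -0.21, with Gstt1 lower adjusted over the list alone, and no longer passed without the wild-type female (-0.12) or the St6galnac6-/- female library (0.05), or with no filter on low values (-0.16, adjusted p = 0.058). The count of 10 genes became 4 and 2 without the wild-type male and female library, with 0 of the 10 kept, and 6 and 4 without the St6galnac6-/- male and female, with 2 kept in each. It became 31 without either B3gnt7-/- library, which enters only the shared spread.

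The B3galt5D116A substitution was set against wild-type. Insl5, a peptide hormone of colonic enteroendocrine cells, rose from 12.02 ± 1.39 FPKM to 49.0 ± 3.99 FPKM (n = 2 each), a log2 change of 1.94 (SE 0.13, limma adjusted p = 0.00693), and Ttr, the thyroid hormone carrier transthyretin, from 21.1 ± 1.67 FPKM to 45.3 ± 6.05 FPKM (log2 1.06). Klk1b22, a kallikrein protease with close paralogs, was listed at 0 in both B3galt5D116A libraries against 21.3 and 25.3 FPKM in wild-type (adjusted p = 3.85e-04). Psca, a cell surface protein, was at 0.326 and 0 FPKM against 10.1 and 7.20 FPKM (adjusted p = 0.00495). Erdr1 fell from 291 ± 69.8 FPKM to 62.5 ± 0.248 FPKM (log2 -2.18), Krt36 to 2.94 ± 0.0346 FPKM (log2 -3.02) and Nr4a1 to 116.05 ± 11.8 FPKM (log2 -1.46). Csrnp1 (log2 -1.40) and Nr4a3 (log2 -2.01) fell as well, which made 9 genes past the threshold, 2 higher and 7 lower, each with the same sign in both sexes, with 1355 at an unadjusted p under 0.05. Insl5 lies on mm10 chromosome 4 from 103017872 to 103026842, Psca on chromosome 15 from 74714839 to 74717069 and Klk1b22 on chromosome 7 from 44112673 to 44116922. Not past the threshold were the glutathione transferase Gsta3 (log2 0.95, adjusted p = 0.0635), Ly6g6c (log2 1.30) and Pop4 (log2 1.60), which, like Klk1b22, lies in a window of 12 Mb on chromosome 7 that held 8 genes with p under 0.001 in B3galt5D116A and B3gnt7-/- together against the other genotypes.

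In B3galt5D116A, camera called 9 of 33 lists, 5 higher and 4 lower. With an estimated correlation it called 0 (smallest adjusted p = 0.706), beside 1355 single genes at an unadjusted p under 0.05. Of 13 enteroendocrine genes, with a median of 0.61, 1 rose over all genes, and 2 rose adjusted over the list alone, Insl5 and the peptide hormone Pyy. For enteroendocrine genes, camera gave adjusted p = 3.96e-04, and adjusted p = 0.706 with an estimated correlation. Pyy was at 65.6 ± 3.71 FPKM against 22.7 ± 6.60 FPKM, and Gcg, which encodes glucagon-like peptides, had a log2 difference of 1.22 (adjusted p = 0.377). Goblet cell genes had a median of 0.31, with 0 called over all genes and 6 higher adjusted over the list alone. For goblet cell genes, camera gave adjusted p = 3.57e-05, and adjusted p = 0.706 with an estimated correlation. Among them were Ang4 (126 ± 91.7 FPKM), Spink4 (2869 ± 503 FPKM) and Reg4 (503 ± 252 FPKM). Proliferation genes were positive in 30 of 30, with a median of 0.74 and 0 called over all genes or adjusted over the list alone. For proliferation genes, camera gave adjusted p = 9.21e-11, and adjusted p = 0.817 with an estimated correlation. The cyclin-dependent kinase Cdk1 was at log2 0.96 and the kinesin Kif11 at log2 0.84. Cholesterol synthesis genes were negative in 22 of 24 with a median of -0.34. Over all genes 0 were called, and Hsd17b7 (log2 -0.70) was lower adjusted over the list alone. For cholesterol synthesis genes, camera gave adjusted p = 2.23e-05, and adjusted p = 0.817 with an estimated correlation. Circadian clock genes were negative in 16 of 17 with a median of -0.45. None passed over all genes, and the clock repressor Nr1d1 (log2 -0.88) was lower adjusted over the list alone. For circadian clock genes, camera gave adjusted p = 8.11e-04, and adjusted p = 0.706 with an estimated correlation. Of the immediate early and heat shock genes, with a median of -0.43, 1 fell over all genes and 13 adjusted over the list alone. For this list, camera gave adjusted p = 3.57e-05, and adjusted p = 0.706 with an estimated correlation. The immediate early members had a median of -0.53 and the 8 heat shock members of 0.71.

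The other lists called in B3galt5D116A had 0 members called over all genes, and adjusted p = 0.706 or more with an estimated correlation. Tight junction genes had a median of -0.21. Endoplasmic reticulum stress genes had 0.21, with the protein disulfide isomerases Pdia4 and Pdia6 higher and Atf3 lower adjusted over the list alone. Antimicrobial genes had 0.28, with 5 higher and 4 lower adjusted over the list alone, and no longer passed with no filter on low values (0.17, adjusted p = 0.193), with quantile normalization (0.28, adjusted p = 0.080) or with no sex term (0.28, adjusted p = 0.059). The count of 9 genes became 3 without the wild-type female library (1 kept), and 6 without the wild-type male (2 kept). Without the wild-type male library 4 lists were called, as cholesterol synthesis (-0.08), enteroendocrine (0.25), tight junction (-0.13), endoplasmic reticulum stress (0.26) and antimicrobial genes (0.22) no longer passed. Endoplasmic reticulum stress and antimicrobial genes also missed the threshold without the wild-type female (0.19 and 0.24) or the B3galt5D116A female (0.08 and 0.22), and antimicrobial genes without either B3gnt7-/- library (0.28).

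The B3gnt7-/- genotype was set against wild-type. Klk1b22 was listed at 0 in both B3gnt7-/- libraries (adjusted p = 3.85e-04), and Psca was at 0.112 and 0 FPKM against 10.1 and 7.20 FPKM (adjusted p = 0.00374). Krt36 fell to 3.26 ± 1.64 FPKM (n = 2) from 31.2 ± 4.63 FPKM (log2 -2.96, SE 0.25), Nr4a1 to 130.0 ± 31.2 FPKM (log2 -1.31) and Csrnp1 to 12.7 ± 2.19 FPKM (log2 -1.46). BC064078, a transcript of unnamed function, was the 1 gene that rose, at 29.6 and 10.9 FPKM against 0 and 0.307 FPKM in the male and female libraries (adjusted p = 0.0372). These 6 genes, 1 higher and 5 lower, had the same sign in both sexes, and 827 genes were at an unadjusted p under 0.05. Csrnp1 lies on mm10 chromosome 9 from 119971163 to 119984658. Insl5 was at 27.7 ± 2.15 FPKM against 12.02 ± 1.39 FPKM without passing (adjusted p = 0.0785). Egln3 (log2 0.73, limma adjusted p = 0.237), Amph (log2 1.12, adjusted p = 0.241) and Pop4 (log2 1.30, adjusted p = 0.244) were higher without passing as well.

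In B3gnt7-/-, camera called 14 of 33 lists, 12 higher and 2 lower. With an estimated correlation it called 0 (smallest adjusted p = 0.336), beside 827 single genes at an unadjusted p under 0.05. Goblet cell genes were positive in 21 of 23 with a median of 0.40, 0 called over all genes and 8 higher adjusted over the list alone. For goblet cell genes, camera gave adjusted p = 5.53e-09, and adjusted p = 0.336 with an estimated correlation. Ang4 was at 42.7 ± 21.8 FPKM, Reg4 at 361 ± 61.6 FPKM and Clca1 at 641 ± 432 FPKM. Interferon response genes were positive in 33 of 40 with a median of 0.36 and 0 called over all genes. Adjusted over the list alone, 4 antiviral genes were higher, Ifit1 (log2 1.09), Oas3 (log2 0.99), Oasl2 (log2 1.06) and Rtp4 (log2 1.03). For interferon response genes, camera gave adjusted p = 1.84e-08, and adjusted p = 0.546 with an estimated correlation. MHC class II genes had a median of 0.99 (1.54 in males and 0.44 in females), with 0 called over all genes and 5 higher adjusted over the list alone. For MHC class II genes, camera gave adjusted p = 2.06e-05, and adjusted p = 0.336 with an estimated correlation. Among them H2-Aa was at 10.4 ± 3.93 FPKM against 3.09 ± 0.850 FPKM. Markers of other cell types moved in the same comparison, but those of fibroblasts and red blood cells rose in the female library and not in the male. T and intraepithelial lymphocyte genes were positive in 11 of 11 with a median of 0.49. For lymphocyte genes, camera gave adjusted p = 2.00e-04, and adjusted p = 0.546 with an estimated correlation. Without the wild-type female library they no longer passed (median 0.16). Myeloid genes had a median of 0.36 over 6 members, with Cd68 higher adjusted over the list alone. Fibroblast genes had 0.77 over 4 (0.03 in males and 1.48 in females) and red blood cell genes 0.95 over 3 (-0.47 in males and 2.37 in females). These 3 lists had 0 members called over all genes, and adjusted p = 0.377, 0.546 and 0.580 with an estimated correlation. With no filter on low values, myeloid genes (0.06, adjusted p = 0.109) and red blood cell genes (0.12, adjusted p = 0.620) no longer passed, nor did red blood cell genes with quantile normalization (1.01, adjusted p = 0.054). The proteoglycan Dcn, of the fibroblast list, was at 10.7 ± 11.6 FPKM against 2.73 ± 0.886 FPKM. Fibroblast genes below the filter were looked at after their values were seen. The collagens Col1a1 and Col3a1 were at 1.58 and 3.61 FPKM in the B3gnt7-/- female library. In the B3gnt7-/- male they were at 0.098 and 0.37 FPKM. Cxcl12 went the other way, at 0.052 FPKM in the female and 0.24 FPKM in the male.

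Genes of O-glycan initiation and core synthesis, which start mucin-type chains, were positive in 16 of 16 in B3gnt7-/-. Their median was 0.14, with 0 called over all genes or adjusted over the list alone, and 0.13, no longer called, without the wild-type male library. For O-glycan core genes, camera gave adjusted p = 5.16e-04, and adjusted p = 0.336 with an estimated correlation. Of the immediate early and heat shock genes, with a median of -0.30, 1 fell over all genes and 8 adjusted over the list alone. For this list, camera gave adjusted p = 1.84e-08, and adjusted p = 0.377 with an estimated correlation. The immediate early members had a median of -0.49 and the 8 heat shock members of -0.15. Proliferation genes were positive in 30 of 30 with a median of 0.39 (0.78 in males and 0.01 in females) and 0 called over all genes or adjusted over the list alone. For proliferation genes, camera gave adjusted p = 3.18e-06, and adjusted p = 0.631 with an estimated correlation. The other lists called had 0 members called over all genes, and adjusted p = 0.377 or more with an estimated correlation. They were stem cell genes (0.15), tuft cell genes (0.45), enteroendocrine genes (0.36, Insl5 higher adjusted over the list alone) and tight junction genes (-0.11, Cldn4 and Ocln lower adjusted over the list alone). Enteroendocrine genes no longer passed without the wild-type male (-0.13), the St6galnac6-/- male or either B3galt5D116A library (0.36 in each). With quantile normalization, enteroendocrine genes (0.37, adjusted p = 0.110) and tight junction genes (-0.02, adjusted p = 0.352) no longer passed.

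The count of 6 genes in B3gnt7-/- became 3 without the wild-type female library (1 kept), 5 without the wild-type male (1 kept), 36 without the B3gnt7-/- male (6 kept) and 11 without the B3gnt7-/- female (4 kept). Without the B3gnt7-/- male library, interferon response (0.16), tight junction (-0.05), proliferation (-0.11) and enteroendocrine genes (-0.10) no longer passed. Without the B3gnt7-/- female, this held for immediate early and heat shock (-0.30), stem cell (0.15), tuft cell (0.05), fibroblast (0.06), myeloid (0.46) and red blood cell genes (0.03). Without the wild-type female it held for tuft cell (0.14), fibroblast (0.40), myeloid (0.24) and red blood cell genes (-0.02).

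**Figure D2:**
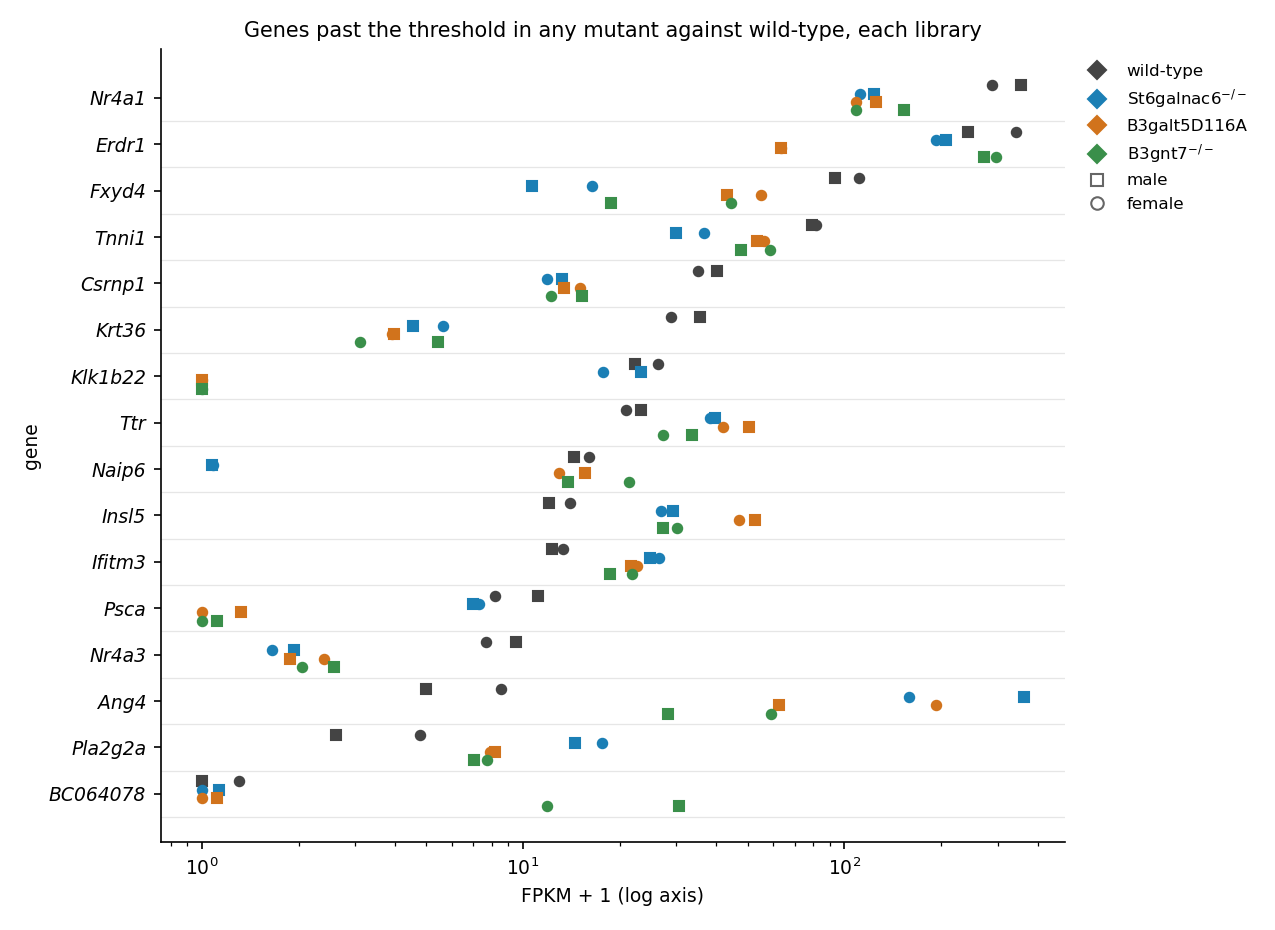
FPKM + 1 on a log axis for each gene past the threshold in any mutant against wild-type, with 1 point per library (colour, genotype; squares male, circles female). Klk1b22 and Psca lay at the bottom of the axis in B3galt5D116A and B3gnt7-/- but not in wild-type or St6galnac6-/-, Naip6 was near 0 in St6galnac6-/-, and Nr4a1, Csrnp1 and Krt36 were lower in all 6 mutant libraries than in both wild-type libraries.

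**Figure D3:**
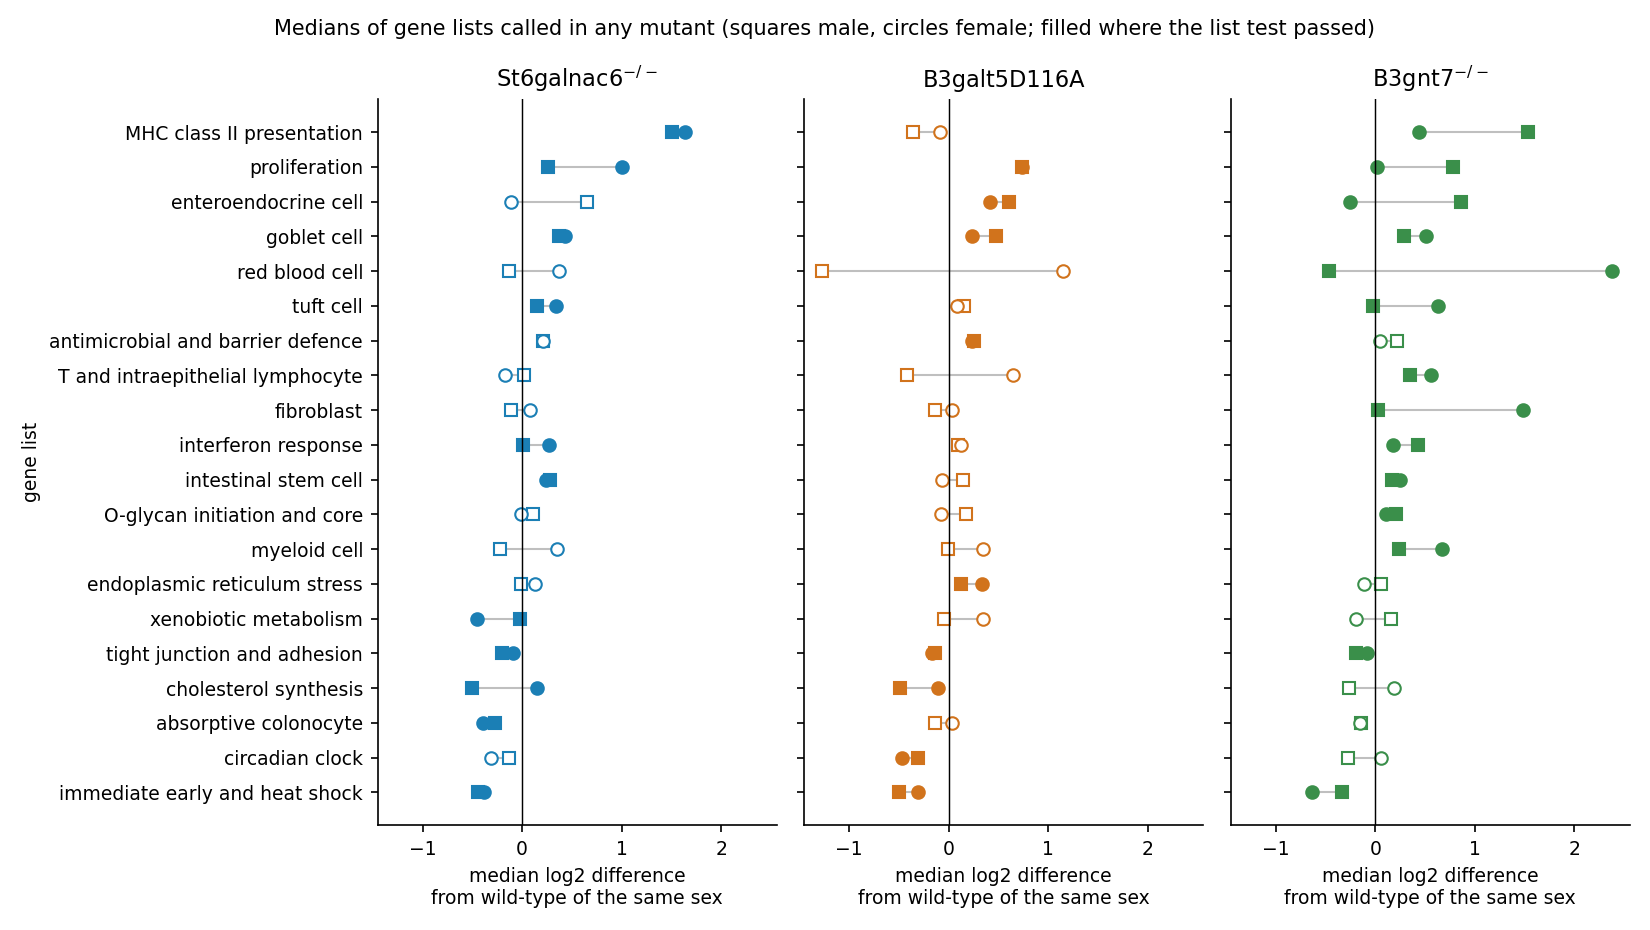
Median log2 difference of each gene list from the wild-type library of the same sex, in males (squares) and females (circles), for lists called by camera with its preset correlation in at least 1 mutant (filled where called). Goblet cell medians were positive in both sexes of all 3 mutants, MHC class II medians were positive in St6galnac6-/- (1.51 and 1.64) and B3gnt7-/- (1.54 and 0.44) and negative in B3galt5D116A, and no call remained with an estimated correlation.

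**Figure D4:**
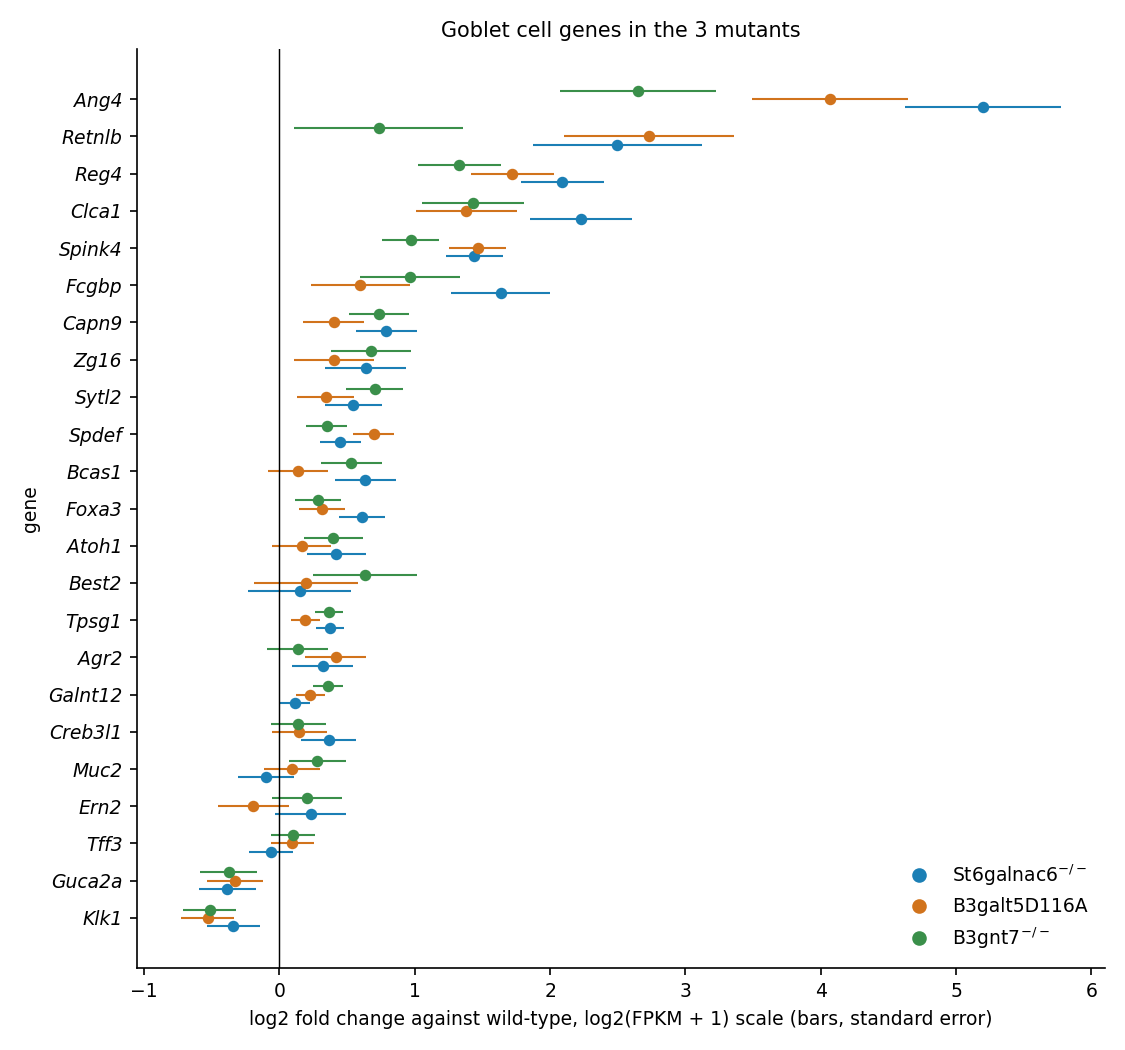
Log2 fold change of each of the 23 tested goblet cell genes in the 3 mutants against wild-type, with bars of 1 standard error. Ang4 had the highest value in each mutant (5.20, 4.07 and 2.65), and of all points only Ang4 in St6galnac6-/- passed the test over all genes.

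The 3 mutants were compared with each other to ask which differences separated them. Klk1b22 was listed at 0 in B3galt5D116A and B3gnt7-/- and was at 22.3 and 16.8 FPKM in St6galnac6-/-, and Psca was at 6.12 ± 0.211 FPKM (n = 2) in St6galnac6-/-, so both were called higher in St6galnac6-/- than in either of the others. Naip6, at 0.0801 ± 0.00240 FPKM in St6galnac6-/-, was at 13.2 ± 1.83 FPKM in B3galt5D116A and 16.6 ± 5.37 FPKM in B3gnt7-/- and was called lower in St6galnac6-/- against each. These were the 3 genes that differed between St6galnac6-/- and B3galt5D116A (405 unadjusted), and with BC064078 and the small nucleolar RNA Snora64, both lower in St6galnac6-/-, the 5 that differed between St6galnac6-/- and B3gnt7-/- (439 unadjusted). Erdr1 was the 1 gene that differed between B3galt5D116A and B3gnt7-/- (62.5 ± 0.248 FPKM against 284 ± 18.4 FPKM, adjusted p = 0.0370; 485 unadjusted). These 3 unadjusted counts lay below the 577 that chance alone gives. MHC class II genes had a median of 1.49 in St6galnac6-/- against B3galt5D116A, with 0 called over all genes and 6 higher adjusted over the list alone. For this difference, camera gave adjusted p = 8.39e-11, and adjusted p = 0.224 with an estimated correlation. Their median in B3galt5D116A against B3gnt7-/- was -0.84, with 0 called over all genes and 4 lower adjusted over the list alone. For that comparison, camera gave adjusted p = 1.61e-07, and adjusted p = 0.417 with an estimated correlation. Absorptive colonocyte genes had a median of -0.33 in St6galnac6-/- against B3galt5D116A, with 0 called over all genes and Slc37a2 lower adjusted over the list alone. For these genes, camera gave adjusted p = 1.86e-08, and adjusted p = 0.224 with an estimated correlation. Against B3gnt7-/- it was -0.24, with 0 called over all genes or adjusted over the list alone. For the latter, camera gave adjusted p = 7.23e-08, and adjusted p = 0.456 with an estimated correlation. In all, camera called 8, 13 and 15 lists in the 3 comparisons and 0 with an estimated correlation. The count of 3 between St6galnac6-/- and B3galt5D116A became 1 without either wild-type library, 9 without the St6galnac6-/- male, 6 without the B3galt5D116A female and 10 without either B3gnt7-/- library. The count of 5 between St6galnac6-/- and B3gnt7-/- became 2 without either wild-type library, 3 without either B3galt5D116A library, 39 without the B3gnt7-/- male and 9 without the B3gnt7-/- female. The call of Erdr1 ended without either wild-type library, either St6galnac6-/- library or the B3galt5D116A male (0 genes called by limma, 314 to 1348 unadjusted) and without the B3galt5D116A female, where 3 other genes were called. It also ended with only the 2 genotypes compared, where 1 other gene was called, and it was kept among 35 and 7 genes without the B3gnt7-/- male and female.

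Nr4a1, Csrnp1 and Krt36 were called lower in all 3 mutants against wild-type. Nr4a3 was called in St6galnac6-/- and B3galt5D116A, and Klk1b22 and Psca in B3galt5D116A and B3gnt7-/-, so that 4, 3 and 5 genes were shared by St6galnac6-/- and B3galt5D116A, St6galnac6-/- and B3gnt7-/-, and B3galt5D116A and B3gnt7-/-. In 100 simulations of unchanged groups, where the 3 comparisons shared 1 simulated wild-type pair, the mean number shared was 0.01, 0.01 and 0.02 and at most 1. The covariance of the log2 fold changes over genes was 0.0649, 0.0565 and 0.0556 against simulated means of 0.02496, 0.0249 and 0.0249. The simulated genes varied independently. Where genes of real libraries vary together, these simulated values are too low a reference, so they do not exclude chance. Both wild-type libraries lay above or both below all 6 others in 15.55% of the tested genes, against 7.14% by chance for any pair. Pairs of unlike genotypes reached more, with 18.8% for B3galt5D116A female and B3gnt7-/- male and 17.9% for wild-type female and B3gnt7-/- female. The 2 wild-type libraries enter all 3 comparisons and cannot be split between them.

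Males and females were compared over all 4 genotypes. The Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty were at 36.0 ± 5.8, 12.4 ± 0.45, 11.4 ± 0.62 and 5.94 ± 0.64 FPKM in males (n = 4) and listed at 0 in all 4 female libraries (limma adjusted p = 6.14e-06, 1.34e-05, 1.34e-05 and 1.95e-04). Xist, the transcript that silences the second X chromosome, was at 67.7 ± 22 FPKM in females and 0.023 FPKM in males (log2 -6.01), so every library matched the sex in its label. Cox6b2, a cytochrome c oxidase subunit, was at 2.85 ± 0.46 FPKM in males and 7.15 ± 1.5 FPKM in females (log2 -1.07, adjusted p = 0.0374). These 6 genes were all that passed, 192 were at an unadjusted p under 0.05, and the histone gene Hist1h4h (log2 0.67) and the X-linked genes Kdm6a (log2 -0.74), Eif2s3x (log2 -0.60) and Kdm5c (log2 -0.46) did not pass. The 192 lay below the 577 of chance. The list of Y-linked and X-inactivation genes had a median of -0.33 but a mean of 0.80 and an upward test direction (camera adjusted p = 0.361; fry adjusted p = 0.00123), with 4 higher and 1 lower over all genes and 4 higher and 5 lower adjusted over the list alone. Camera called 4 lists, of which immediate early and heat shock genes were higher in males (median 0.19) with 0 members called over all genes or adjusted over the list alone. For this sex difference, camera gave adjusted p = 7.47e-06, and adjusted p = 0.828 with an estimated correlation. MHC class II genes had a median of 0.19, goblet cell genes of -0.09 and proliferation genes of -0.09 (adjusted p = 0.0274 for each; adjusted p = 0.828 or more with an estimated correlation). Whether a genotype acts differently in males and females was not tested, since each genotype and sex had 1 library.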

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

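The tests of heat shock genes, of the wild-type libraries as a pair and of the chromosome 7 segment were chosen only after the results they concern were seen.

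Ddx3y in males stood out for the B3gnt7-/- male library, at 11.68 FPKM, far below the other 3 for so narrow a range (12.6 FPKM in each). Uty in males stood out for the St6galnac6-/- male library, at 6.89 FPKM against 5.55 to 5.76 FPKM in the others. In 16 sets of 4 libraries checked this way, chance alone picks out about 1 in 20. T and intraepithelial lymphocyte genes moved in opposite directions in the sexes in B3galt5D116A, with a female minus male median of 1.06 (-0.41 in males and 0.64 in females). Red blood cell genes did so in B3galt5D116A, with a female minus male median of 2.41 (-1.27 in males and 1.14 in females), and in B3gnt7-/-, with 2.84 (-0.47 in males and 2.37 in females). These 3 differences between the sexes, out of 99 combinations of list and mutant examined, were not tested, since each rests on 1 library per genotype and sex.

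Immediate early genes were lower in all 3 mutants than in wild-type, with both wild-type libraries above the other 6 for 16 of 22 members. Over all tested genes this held for 960 of 11537, where chance gives 3.57% per gene. The members may vary together and were seen to be lower first, so the 16 are not independent. Their list, with the heat shock genes, had adjusted p = 0.649, 0.706 and 0.377 with an estimated correlation, and Nr4a1 was its 1 member called over all genes in each mutant. A lower depth of the wild-type libraries is argued against by the 15 members with a mean of at least 50 FPKM, all of which were lower, with a median of -0.55 over the mutants. A stress response that lowers heat shock genes too is argued against in St6galnac6-/- and B3galt5D116A by opposite directions. There 8 heat shock genes had a median of 0.73, 1.29 above the immediate early members. The bootstrap interval of 0.97 to 1.66 resampled genes and not libraries, so it does not measure the spread between libraries. Both mutants were also set against the same wild-type libraries. A stress response in which heat shock and immediate early genes move apart was not tested and stays open in every mutant. A shared stress response stays open in B3gnt7-/-, where the heat shock median was -0.15, with 0.94 in the male library and -1.23 in the female. A separate preparation of the wild-type libraries and an effect shared by the mutants cannot be told apart, since the labels name no batch: both wild-type libraries lay outside the other 6 in 15.55% of genes, and the widest of the other pairs, B3galt5D116A female and B3gnt7-/- male, in 18.8%, which does not exclude a batch of the wild-type libraries.

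MHC class II genes were higher in St6galnac6-/- and B3gnt7-/-, with medians of 1.57 and 0.99, although neither list call remained with an estimated correlation. Antigen-presenting immune cells carried over with the epithelium may be a source, and the labels name no sort that would remove them; epithelial cells can also make these transcripts. The summed FPKM of 12 markers of B cells, macrophages and dendritic cells had a log2 ratio to wild-type of -0.33 in St6galnac6-/-. In B3gnt7-/- it was 0.20, the mean of -0.56 in the male and 0.96 in the female library. At a mean of 0.11 FPKM per marker, these markers lie near the floor and exclude nothing. The sum of 8 abundant leukocyte transcripts, at a mean of 1.26 FPKM each, had a ratio of -0.093 in St6galnac6-/- (0.28 in the male and -0.47 in the female library) and 0.72 in B3gnt7-/- (0.43 and 1.02). Immune cells and an epithelial change thus cannot be told apart in either mutant. In St6galnac6-/- the leukocyte sum differed in sign between the sexes. In B3gnt7-/- it rose in both sexes, but more in the female, whereas MHC class II genes rose more in the male. The lymphocyte and myeloid lists were called higher in B3gnt7-/- at the preset correlation, and neither call remained with an estimated correlation.

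Klk1b22 and Psca differed from wild-type and St6galnac6-/- in both B3galt5D116A and B3gnt7-/-. Of 27 genes with p under 0.001 with those lines set together against the other genotypes, a comparison that also picks up a change in 1 of the other genotypes alone, 8 lay in 1 window of 12 Mb on chromosome 7 (34674468 to 45694556), against a 95th percentile of 3 with shuffled positions (permutation p = 1e-04, the smallest that 10000 shuffles can give); they were Chst8, Pop4, Zfp939, Klk1b22, Josd2, Emc10, Rras and Ntn5. Rras was also lower than wild-type in St6galnac6-/- (log2 -0.68, against -0.83 in B3gnt7-/-), so its change is not particular to the 2 lines. Josd2 was lower than wild-type in St6galnac6-/- (log2 -0.37), which adds to its difference. Ntn5 in the B3gnt7-/- male (1.26 FPKM) was near the St6galnac6-/- male (1.34 FPKM). The count of 8 may thus overstate a shared change. For Chst8, Pop4, Zfp939, Klk1b22 and Emc10, all libraries of the 2 lines lay outside the range of the other genotypes. A candidate explanation is a chromosome 7 segment of another origin shared by the 2 lines, and the window was found and tested on the same data. Reads shared within the Klk1 family are argued against as the whole source, since 7 of the 8 genes lie outside it. They may contribute for Klk1b22 itself. Paralogs of the other 7 genes were not examined, so shared reads are not excluded for those. The other 78 genes of the span had a median absolute t of 0.90, which 15.1% of random runs exceeded, so most genes there did not stand out, and Psca lies on chromosome 15.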

How the results depend on the processing

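Alternatives were planned before the data were examined, except that the tests without small RNA genes were chosen after the result was seen, and fits of only the 2 genotypes compared were planned against wild-type alone and added between mutants. No alternative chosen beforehand for a result was left unrun, but fewer were chosen for lists and single genes than for counts: a pseudocount of 5, a mean FPKM of at least 5, median centring, fits of only the 2 genotypes compared and the prior variances were run for counts of genes alone. Of the log2 fold changes of named genes, 1815 values under an alternative kept direction and side of the threshold, 112 fell short of it, 42 passed it and 0 turned direction. Of the called lists, 358 values kept both, 44 fell short and 6 turned the direction of the test, while 7 medians changed sign, 2 of them among the 44; of the counts, 112 stayed within 1.5 times and 62 did not. The cause was not tested for any change below, except that no filter adjusts over 17801 genes and a left-out library leaves a group with 1, assumed to vary like the others.

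Against wild-type, the count of genes was 10 in St6galnac6-/-, 9 in B3galt5D116A and 6 in B3gnt7-/-. With no filter on low values it became 0, 1 and 2 (limma, 1406, 1627 and 1242 unadjusted). With no sex term it became 23 in St6galnac6-/- and 16 in B3galt5D116A. With a constant prior variance it became 6 in St6galnac6-/- and 3 in B3gnt7-/-, with quantile normalization 5 in St6galnac6-/-, with only the 2 genotypes compared 49 in St6galnac6-/-, and with a mean FPKM of at least 5 it became 3 in B3gnt7-/-. Leaving out 1 library gave 2 to 31 in St6galnac6-/-, 3 to 13 in B3galt5D116A and 3 to 36 in B3gnt7-/-.

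Between mutants, the count was 3 for St6galnac6-/- against B3galt5D116A, 5 for St6galnac6-/- against B3gnt7-/- and 1 for B3galt5D116A against B3gnt7-/-. With no filter it became 1, 1 and 0 (849 unadjusted for the last). For St6galnac6-/- against B3galt5D116A it became 5 with a pseudocount of 0.1, 5 with a robust prior variance, 5 without small RNA genes, 7 with no sex term and 10 with only the 2 genotypes compared. For St6galnac6-/- against B3gnt7-/- it became 3 with a pseudocount of 5, 2 with a mean FPKM of at least 5 and 8 with only the 2 genotypes compared. For B3galt5D116A against B3gnt7-/- it became 0 with quantile normalization (470 unadjusted) and 0 with a constant prior variance (499 unadjusted), and 2 with no sex term and 2 without small RNA genes. Leaving out 1 library gave 1 to 10, 2 to 39 and 0 to 35 (314 to 1348 unadjusted where 0). Between the sexes every alternative stayed within 1.5 times of 6, with 5 to 6 when 1 library was left out. Each fit with a left-out library kept only 5 of the 6 calls. With a pseudocount of 5, no filter or quantile normalization, 5 calls were kept, with 1 lower in males. With a mean FPKM of at least 5, 4 were kept. The genes called lower in males were Xist and Cox6b2, of which Cox6b2 had the larger p.

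Camera called 11, 9 and 14 lists in the 3 mutants against wild-type. With an estimated correlation it called 0, 0 and 0, and fry for a move one way called 1, 0 and 0 (1043, 1355 and 827 single genes were at an unadjusted p under 0.05). Fry's mixed test, which gives no direction, called 9, 7 and 5 lists, and 0 in each comparison between mutants. With camera at the preset correlation, leaving out 1 library gave 9 to 14 lists in St6galnac6-/-, 4 to 13 in B3galt5D116A and 10 to 14 in B3gnt7-/-. In St6galnac6-/-, the cholesterol synthesis median ran from -0.38 to 0.10 over the left-out libraries, turning direction without the wild-type male (0.10) and the St6galnac6-/- male (0.02); the interferon response median from 0.0075 to 0.36, with the test direction turned without the St6galnac6-/- female (0.0075); and the xenobiotic metabolism median from -0.44 to 0.046, turning without the St6galnac6-/- female (0.046). In B3gnt7-/-, the proliferation median ran from -0.11 to 0.88 and the enteroendocrine median from -0.13 to 0.89, and both turned without the B3gnt7-/- male (-0.11 and -0.10). Without the wild-type male the enteroendocrine median was also negative (-0.13), as was the red blood cell median without the wild-type female (-0.02), with upward test directions that did not pass.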

Other observations

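The way of fitting splits of the libraries that follow genotype was changed after the result was seen, and the genes named from the glycosylation lists, the heat shock genes and the chromosome 7 genes were chosen after their values were seen.

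The lists of glycosylation enzymes to which the targeted genes belong were not called in the mutants against wild-type, except the O-glycan core list in B3gnt7-/-. That list had adjusted p = 0.336 with an estimated correlation, and without the wild-type male library it no longer passed (median 0.13, adjusted p = 0.051). Sialyltransferases had medians of -0.09, 0.10 and -0.02 in St6galnac6-/-, B3galt5D116A and B3gnt7-/- (means -0.20, -0.04 and -0.06; upward test directions in the last 2), and chain extension enzymes of -0.02, 0.00 and 0.10. Fucosylation genes had medians of 0.10, 0.10 and 0.08, sulfation genes of -0.09, -0.02 and -0.08, and membrane mucins of -0.02, -0.04 and 0.04. Adjusted over the list alone, the sialyltransferase St8sia5 was lower in St6galnac6-/-, at 0.0947 and 0.0424 FPKM in the male and female against 1.89 and 5.61 FPKM in wild-type, as were B3gnt2, B3gnt6 and B4galt1, which build and extend glycan chains. The sulfotransferase Chst8 was lower in B3galt5D116A and B3gnt7-/- (0.26 and 0.34, and 0.27 and 0.32 FPKM, against 2.87 and 3.04 FPKM in wild-type), and Hs3st1 in B3gnt7-/-. Chst8 lies in the chromosome 7 window described above. None of these single genes passed over all genes in a mutant against wild-type, and the adjustment over a list alone does not account for the number of lists.

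Heat shock genes went apart from the immediate early genes of their list in St6galnac6-/- and B3galt5D116A, but not in both B3gnt7-/- libraries. Hspa1a, an inducible chaperone, was at 153 and 237 FPKM in the wild-type male and female, at 446 and 466 FPKM in St6galnac6-/-, at 368 and 358 FPKM in B3galt5D116A, and at 468 and 77.9 FPKM in B3gnt7-/-. Hspb1, a small heat shock protein, was at 8.54 and 16.1 FPKM in wild-type, 49.2 and 49.2 FPKM in St6galnac6-/-, 44.9 and 43.0 FPKM in B3galt5D116A, and 57.3 and 3.002 FPKM in B3gnt7-/-. Neither passed the limma test in any mutant. The transcription factor Ciita, which switches on MHC class II genes and lay below the filter, was at 0.083 and 0.079 FPKM in wild-type, 0.39 and 0.53 FPKM in St6galnac6-/-, 0.029 and 0.050 FPKM in B3galt5D116A and 0.25 and 0.19 FPKM in B3gnt7-/-.

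Lists not called numbered 22 in St6galnac6-/-, with medians from -0.20 to 0.56 (smallest adjusted p = 0.0516, for enteroendocrine genes), 24 in B3galt5D116A, from -0.23 to 0.27 (0.195), and 19 in B3gnt7-/-, from -0.19 to 0.31 (0.227). These included smooth muscle, endothelial and squamous epithelium markers in all 3 mutants, posterior Hox genes, ion and water transport, fatty acid oxidation and sex hormone response.

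The 6 genes that differed between males and females were set against other splits of the 8 libraries into 4 and 4: 2 of 35 splits gave as many, the real one with 6 and another with 7, so chance cannot be excluded by that count. The split with 7 put wild-type and St6galnac6-/- against B3galt5D116A and B3gnt7-/-, so it follows genotype. It was 1 of 3 such splits, which were fitted as comparisons of genotypes in the model with genotype and sex. They had first been fitted with neither term, where it gave 5 and 1 of 35 splits, the real one, gave as many, so the answer depends on that choice. The count does not bear on 5 of the 6 genes taken singly: Eif2s3y, Ddx3y, Kdm5d and Uty, which are Y-linked, were each listed at 0 in all 4 female libraries, and Xist was at 67.7 FPKM in females against 0.023 FPKM in males.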
